A study of Mus musculus with 188 samples.

How the data were processed

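RNA from the aorta of male mice aged 16 weeks, kept on chow, had been hybridised to 188 Affymetrix HT_MG-430A arrays. The mice belonged to 94 inbred and recombinant inbred strains. Per the submitters' processing notes, the arrays were read with GCOS and summarised by RMA, whose versions and genome build are not given in the sources used here. The deposited values are log2 expression values, with 1 value per probe set and array in a single table of the series, RMA being a procedure of background adjustment, quantile normalisation and summary of each probe set's probes. Array medians lay between 4.55 and 4.88. The table gave 22416 probe sets, of which 89 Affymetrix control probe sets were left out, so 22327 were tested. No array column lacked a label. Probe sets were named from the platform's gene annotation. Of these, 17783 carried 1 gene symbol, 284 carried several and 4260 were not listed there, and the named probe sets covered 11725 genes. Symbols were looked up by Entrez ID in a mouse gene table of assembly GRCm38.p6, which held 17759 of the probe sets with 1 symbol and changed 0 symbols. That table was used for symbols and for which genes neighbour each other only.

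Groups were the strains written in the labels. Nothing in the labels says that the arrays of a strain came from separate animals, so the p-values below measure only the spread between these arrays, which may be partly technical. The number of arrays per strain, mostly 2, limits the precision of each strain mean. The 2 BXD32/TyJ arrays carry an unexplained suffix in their descriptions and were left out of the main fits. They are among the 79 strains with 2 arrays and the 188 arrays over which scores were compared or correlated. The most similar pair of arrays (r = 0.994, BXH4/TyJ) still differed by up to 4.67 on the log2 scale, so no arrays were merged as duplicates.

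Computations were done in R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. Benjamini-Hochberg adjusted p-values below 0.05 were called. The strain effect was limma's moderated F test across the 84 strains with 2 or more arrays (177 arrays), and the intraclass correlation (ICC), the share of a probe set's variance that lies between strains, came from one-way variance components with 95% intervals. Parental contrasts (A/J, DBA/2J and C3H/HeJ, 2 arrays each, against the 3 C57BL/6J arrays) were limma contrasts in a fit of all strains with 93 residual degrees of freedom. Segregation was tested as the moderated F test within each recombinant inbred family, without parental arrays, and the shares passing were given with exact binomial intervals. These intervals, and those of the shares of matching signs between families and parents, take probe sets as independent. Probe sets of the same gene or of neighbouring genes are not, so the intervals may be too narrow. Families were contrasted on 1 mean per strain. The difference between families in the variance of strain means was tested by moving strains between families at random (100000 resamples, two-sided), as were correlations of list scores, where a score is the mean of the members' centred log2 values. Gene lists were compared with 10000 random lists of the same size matched on mean level. They were tested on the parental contrasts with camera, with a preset correlation of 0.01 and with an estimated correlation, for lists with at least 3 measured members, each member being represented by its probe set with the highest mean.

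Exclusions, the naming rule, most gene lists, most tests and most alternatives were fixed before the data were examined. The closing section names the tests chosen later. Only probe sets with 1 symbol were named, with the strongest probe set standing for a gene. For the strain effect these were the 20 genes with the largest among-strain standard deviation (SD). For each parental contrast they were the 10 genes with the largest increase and the 10 with the largest decrease. For segregation they were the 4 genes with the largest parental difference in each family, and for the family contrasts the 5 largest each way for AXB/BXA against BXD and the 3 largest each way for the other pairs. Named in addition were 2 to 4 members of each fixed list, members that did not pass, and Tlr4 and Cep290, whose alleles are written in strain names. The fixed lists were smooth muscle contractile, elastic fibre and matrix, thoracic aortic disease genes, endothelial, adventitial fibroblast, macrophage, lymphocyte, brown adipocyte, adipocyte, skeletal muscle, cardiac muscle, erythroid, Schwann cell, interferon response, major histocompatibility complex (MHC), vascular inflammation, xenobiotic and antioxidant, sterol synthesis, cell cycle, circadian clock, immediate early and heat shock, a sex chromosome check and the 2 strain label alleles. Lists of thymocyte, thymus, squamous epithelium and skin genes were added after the data had been seen.

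The procedures were tested on simulated data with the real probe sets' levels and spreads, with 50 changed probe sets per size among 22327. For A/J against C57BL/6J, 54% of simulated log2 changes of 1 were recovered, 94% of 2, 96% of 3 and 86% of -2, with 12 unchanged probe sets called. For the strain effect, 10% were recovered at an ICC of 0.2, 38% at 0.3, 98% at 0.5 and 100% at 0.7, with 12 unchanged probe sets called. The adjustment is less strict when more probe sets change, and 10375 passed in the real data. These shares therefore understate the recovery there: all 8 measured brown adipocyte genes passed, with a lowest ICC of 0.203. For AXB/BXA against BXD, 52% of log2 changes of 0.25, 88% of 0.5, 88% of -0.5 and 100% of 1 were recovered, with 3 unchanged probe sets called.

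Processing alternatives were a filter on dim probe sets, a further quantile normalisation, 1 probe set per gene, trended or robust moderation, an adjusted p threshold of 0.01, the BXD32/TyJ arrays kept, strains AXB19a/PgnJ and AXB19b/PgnJ left out, only strains with 2 or more arrays, only strains with consecutive array numbers, only the 9 parental arrays, the array number block as a covariate, the adipocyte, skeletal muscle and erythroid scores as covariates, each parental array left out in turn, every probe set of a list member, the first principal component of a list as its score, and random pairs of arrays in the control for array numbers. Alternatives added after the data had been seen were the thymocyte, squamous epithelium and skeletal muscle scores as covariates, the omission of arrays above 1 on the thymocyte or squamous epithelium score, and the omission of the array with the lowest correlations. Array numbers fall into blocks from 925 to 1038 (92 arrays, 49 strains) and from 1067 to 1168 (96 arrays, 50 strains), with 5 strains in both, which served as the only batch that the labels give. Genotypes of the strains were not used here, so no transcript was mapped to a locus.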

Results

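RNA levels in the mouse aorta were profiled on 188 arrays from 94 strains of the Hybrid Mouse Diversity Panel, a collection of classical inbred and recombinant inbred strains, in males aged 16 weeks. Of the strains, 9 had 1 array, 79 had 2, 3 had 3 and 3 had 4. Of these, 28 AXB and BXA strains (59 arrays) descend from crosses of A/J with C57BL/6J, 28 BXD strains (53 arrays) from crosses of DBA/2J with C57BL/6J, and 10 BXH strains (21 arrays) from crosses of C3H/HeJ with C57BL/6J. The other 28 strains (55 arrays) were inbred strains that included these 4 parents. Levels spanned 2.17 to 13.5 on the log2 scale. Each array's mean correlation across probe sets was 0.813 to 0.990 (median 0.973) with arrays of its own strain and 0.819 to 0.965 (median 0.957) with arrays of other strains. These are correlations across genes within arrays and not across replicates. The array with the lowest values was C57L/J replicate 1.

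The first question was how far aortic transcript levels differed between strains, since the panel serves to associate such differences with genotype. The widest differences included histocompatibility genes. H2-D1, a class I histocompatibility gene, ran from 3.20 ± 0.13 in AXB6/PgnJ to 10.83 ± 0.24 in AXB12/PgnJ (strain mean ± SD, n = 2 each, log2), with an ICC of 0.892 (95% interval 0.840 to 0.928). H2-Ea, the alpha chain of a class II molecule, ran from 2.82 in BXD2/TyJ to 10.86 in SEA/GnJ (ICC 0.816). H2-Q10, a class I gene of the Q region, ran from 3.49 in BXD34/TyJ to 9.86 in AXB6/PgnJ (ICC 0.817). Uqcr10, a subunit of the ubiquinol-cytochrome c reductase of the respiratory chain, ran from 3.47 ± 0.26 in RIIIS/J to 9.75 ± 0.08 in BXD29-Tlr4<lps-2J>/J (ICC 0.944). Pttg1, the separase inhibitor securin, ran from 5.48 in NZW/LacJ to 11.68 in BXD40/TyJ (ICC 0.851). The chemokine Cxcl14 ran from 4.32 in BXA13/PgnJ to 11.30 in BXD20/TyJ, the interferon-inducible Ifi205 from 2.51 in SM/J to 7.67 in BXA7/PgnJ. The serine protease inhibitor Serpina1b ran from 3.20 in BXH22/KccJ to 9.71 in BTBR T<+> tf/J. These ranges hold for the most variable probe set of each gene. Brighter probe sets of H2-D1 and Uqcr10, with means of 10.6 and 12.4, were not called between A/J and C57BL/6J (log2 difference -0.30 and -0.02; limma). The ranges of these genes as a whole are therefore uncertain.

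The other 12 of the 20 genes with the largest among-strain SD had various functions. Pdxdc1 had the highest ICC of the 20, 0.977, with 3.08 in BXD13/TyJ and 7.94 in BXD29-Tlr4<lps-2J>/J, followed by Rpgrip1 at 0.955. Between DBA/2J and C57BL/6J this Pdxdc1 probe set differed by 4.01 and a second 1 by -3.96, so the gene's level is uncertain. Erdr1 (3.91 in BXD20/TyJ to 11.73 in AXB13/PgnJ), Gdpd3 (3.68 in AXB15/PgnJ to 11.40 in RIIIS/J), Tmem45b (3.85 in NZW/LacJ to 11.17 in NON/ShiLtJ), Tmem87a (ICC 0.917), Abhd1 (ICC 0.882), the peptide transporter Slc15a2 (3.23 in CBA/J to 8.21 in C58/J) and the gluconeogenic bisphosphatase Fbp1 (2.97 in SWR/J to 9.12 in BXA14/PgnJ) also differed. The alpha globin gene Hba-a1 ran from 7.40 in BXD20/TyJ to 13.08 in KK/HlJ. Nppa, the atrial natriuretic peptide, ran from 4.01 in AXB19/PgnJ to 13.07 in MA/MyJ, but its within-strain SD of 1.80 was as wide as its among-strain SD of 1.78 (ICC 0.495). Ada, adenosine deaminase, had the widest within-strain SD of the 20, 2.34, and an ICC of 0.301 (0.108 to 0.476). Across the 188 arrays Ada followed a score of squamous epithelial genes (r = 0.919, rho = 0.640, permutation p = 1e-05 for each, the smallest possible, adjusted p = 1e-05 over 6 relations). It was 0.914 without the 2 most extreme arrays and 0.921 and 0.924 within the blocks of array numbers. Its strain effect was no longer called (ICC 0.0591, adjusted p = 0.391) without the 73 arrays above 1 on the thymocyte or squamous score. This setting, chosen after the data had been seen, is called below the omission of arrays high in thymocyte or squamous genes.

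In all, 10375 of 22327 probe sets (46.5%), naming 6228 genes, differed between the 84 replicated strains (limma's moderated F test), against 12181 at an unadjusted p below 0.05 where 1116 would be expected by chance. The median ICC was 0.182 over all probe sets, 1031 exceeded 0.5 and 90 exceeded 0.8. Among called probe sets the median among-strain SD was 0.25 and the median within-strain SD 0.37. Calls were more frequent among probe sets above the median level (7809) than below it (2566). Arrays of a strain usually carry consecutive numbers. The test was therefore repeated on 77 false pairs of neighbouring arrays from different strains. It called 86 probe sets (4337 at an unadjusted p below 0.05), against 4121 (7531) for the 59 true strains on 122 of the same arrays and 0 (635) for random pairs, with median ICCs of 0.0807, 0.130 and -0.0234. Arrays with neighbouring numbers thus resembled each other beyond their strain. With only strains of consecutive numbers the count was 6852, without the arrays high in thymocyte or squamous genes 6865, and with 1 probe set per gene 5759.

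Genes of the arterial wall were tested next, with each list's median ICC ranked among random lists matched on level. Members of a list can move together, which the random lists do not copy. The correlation estimated by camera was 0.870 for the skeletal muscle list, though 0.0143 for the clock list. Extreme percentiles may therefore overstate how unusual a list is. Of the smooth muscle contractile genes, 10 of 13 measured passed (10 when adjusted over the list alone), with a median ICC of 0.232 at percentile 31.1. BXH22/KccJ had the lowest mean for 7 of these 10, among them smooth muscle actin Acta2 (11.24 against 12.94 in BXH2/TyJ), calponin Cnn1 (6.11 against 10.13 in BXH2/TyJ), the potassium channel subunit Kcnmb1 (3.52 against 7.05 in KK/HlJ) and the myosin heavy chain Myh11 (7.48 against 10.14 in BXA4/PgnJ). Itga8, Des and Synpo2 did not pass. Both BXH22/KccJ arrays were low on the smooth muscle score (-1.30 and -1.75), and replicate 2 was high on the thymocyte score (3.07). Without the arrays high in thymocyte or squamous genes, 9 of the 10 lost their call, all but Actg2. The ICC turned negative for Acta2 (-0.033), Lmod1 (-0.011), Myh11 (-0.11) and Mylk (-0.038). The adjusted p was 0.476 for Cnn1, 0.0747 for Kcnmb1, 0.507 for Myl9, 0.132 for Tpm2 and 0.185 for Myocd. Over all probe sets this omission, which dropped 73 of the 188 arrays, lowered the count from 10375 to 6865. Losses in any list are to be read beside that fall, since fewer arrays and strains enter. With the thymocyte, squamous epithelium and skeletal muscle scores as covariates the count was 10653, and all 9 genes kept their call. Of the elastic fibre and matrix genes 18 of 19 passed (19 when adjusted over the list alone; median ICC 0.314, percentile 85.7), including elastin Eln (7.77 in BXH22/KccJ to 10.65 in BXH2/TyJ), Fbln5 (7.38 in RIIIS/J to 9.69 in AKR/J) and Col1a1 (7.13 in RIIIS/J to 10.51 in AKR/J). Ogn did not pass. Under the same omission 6 of the 18 lost their call: Eln (adjusted p = 0.0538), Mfap4 (0.140), Lox (0.0563), Bgn (0.419), Postn (0.0823) and Emilin1 (0.116). All 6 kept it with the same covariates.

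RIIIS/J had the lowest mean for 9 of the 10 endothelial genes that passed, out of 12 measured (10 when adjusted over the list alone; median ICC 0.306, percentile 82.7), such as the growth factor receptor Kdr (6.30 against 8.33 in BXD12/TyJ), Cdh5 (4.45) and Nos3 (5.30 against 8.07 in KK/HlJ). Pecam1 and Icam2 did not pass. RIIIS/J was also lowest for 6 of the 7 adventitial fibroblast genes that passed out of 8 measured (7 when adjusted over the list alone; median ICC 0.301, percentile 82.7), such as Clec3b (4.97 against 8.02 in C3H/HeJ) and Serpinf1 (7.80). Pi16 did not pass. Both RIIIS/J arrays had high thymocyte scores (5.41 and 5.68), the latter being the highest of all arrays. Of the genes of inherited thoracic aortic disease, 7 of 12 passed (7 when adjusted over the list alone; median ICC 0.211, percentile 53.0), including Tgfbr2 (8.49 in RIIIS/J to 9.69 in C58/J), Tgfb3 (5.19 in RIIIS/J to 8.02 in AKR/J) and Col3a1. The genes Tgfbr1, Slc2a10, Prkg1, Foxe3 and Smad3 did not. Without the arrays high in thymocyte or squamous genes, 7 of the 10 endothelial genes lost their call: Egfl7 (adjusted p = 0.206), Eng (0.0540), Esam (0.0827), Nos3 (0.197), Emcn (0.178), Tek (0.0776) and Tie1 (0.114). So did 6 of the 7 thoracic aortic disease genes: Tgfbr2 (0.0920), Tgfb3 (0.0503), Lox (0.0563), Acta2, Myh11 and Mylk. Of the adventitial fibroblast genes Dpt did (0.0940). With the thymocyte, squamous epithelium and skeletal muscle scores as covariates all these genes kept their call.

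Immune genes differed in part. Of 16 macrophage genes 14 passed (14 when adjusted over the list alone), and their median ICC of 0.347 lay at percentile 99.6 of random lists. Lyz2, Cd68 (5.25 in CE/J to 8.79 in BTBR T<+> tf/J) and the receptor Csf1r (5.12 in CE/J to 8.25 in BTBR T<+> tf/J) were among them. Msr1 and Fcgr1 did not pass. Of 10 lymphocyte genes 6 passed (9 when adjusted over the list alone; median ICC 0.289, percentile 91.4), among them the antibody joining chain Jchain (3.98 in AXB23/PgnJ to 10.16 in BXD2/TyJ) and the B cell gene Ms4a1 (3.58 in BXD20/TyJ to 7.73 in BXH4/TyJ). The T cell genes Cd3d, Cd3e and Cd3g and the immunoglobulin gene Ighm did not pass. Of 10 MHC genes 9 passed (9 when adjusted over the list alone; median ICC 0.436, percentile 99.9), with H2-T23 (6.74 in AXB24/PgnJ to 10.55 in C57L/J) and H2-Eb1 (4.49 in FVB/NJ to 10.15 in SJL/J) after H2-Ea. H2-Q1 did not pass. Of 13 interferon response genes 10 passed (11 when adjusted over the list alone; median ICC 0.239, percentile 83.3). BXA2/PgnJ had the highest mean of Ifit3 (6.19), Usp18 (6.49), Irf7 (5.41), Mx1 (4.30) and Ifit1 (6.71). Even this mean of Mx1 lay below the 4.63 that Xist, a transcript of females, reached in these males. The differences of Mx1 are therefore near background. Of 12 vascular inflammation genes 4 passed (3 when adjusted over the list alone; median ICC 0.109, percentile 31.3): Nfkbia, Selp, Csf1 and Icam1. In the omission of arrays high in thymocyte or squamous genes, the interferon genes Irf7 (adjusted p = 0.189), Mx1 (0.399) and Ifi47 (0.107) and the macrophage genes Ctss (0.0557), Itgam (0.439) and Mrc1 (0.378) lost their call. Ifit1 lost it in 9 settings, such as the array number block as a covariate (0.0569), where Irf7 did too (0.0532), and Laptm5 in 12.

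**Figure D1:**
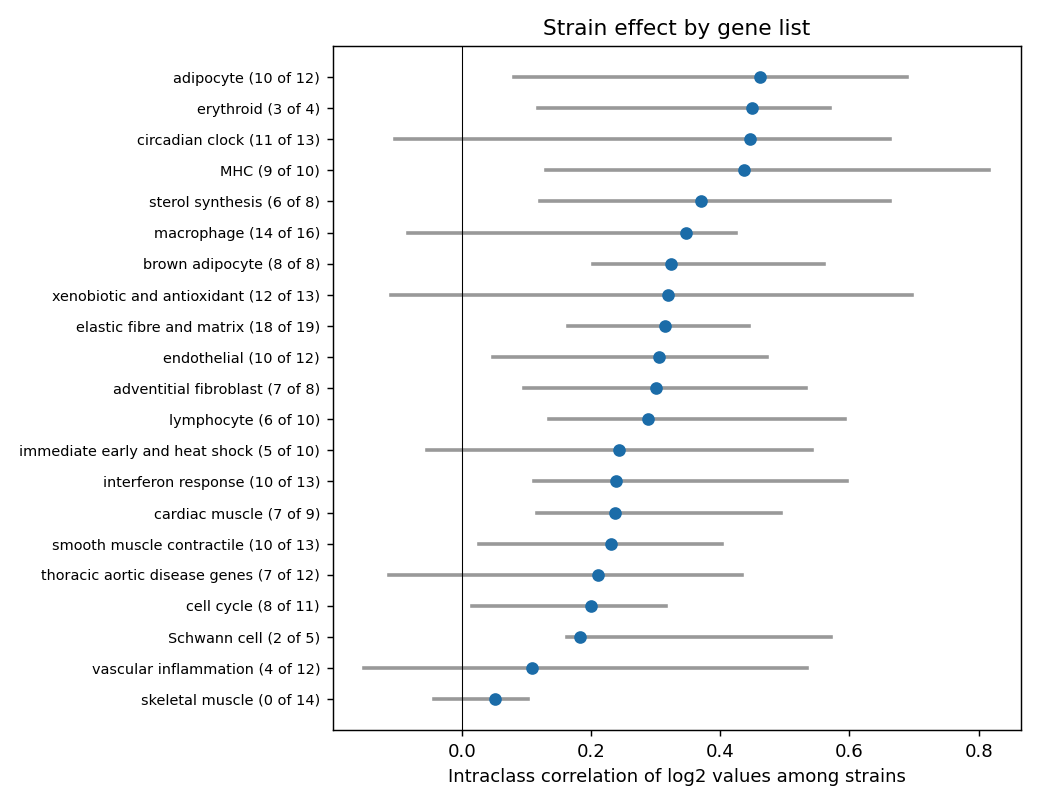
Intraclass correlation of the members of 21 gene lists across 84 strains. The dot is the list's median, the grey line runs from its lowest to its highest member and the label gives members passed of members measured; the adipocyte list is highest at 0.462 and the skeletal muscle list lowest at 0.0512.

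Fat genes were bright. All 8 measured brown adipocyte genes passed (8 when adjusted over the list alone; median ICC 0.324, percentile 81.5), and the uncoupling protein Ucp1 averaged 12.67 and Cidea 12.36 over the arrays. Elovl3 had the widest range, from 6.91 in BXD42/TyJ to 11.25 in BXH7/TyJ, and Ucp1 was lowest in NOD/ShiLtJ (11.24). With the arrays high in thymocyte or squamous genes omitted, Ucp1 (adjusted p = 0.260), Cox7a1 (0.158) and Cox8b lost their call, as they did with only strains of consecutive numbers (0.132, 0.114 and 0.125). Ucp1 also lost it with the array number block as a covariate (0.0546), with the BXD32/TyJ arrays (0.0519) and without C57BL/6J replicate 1 or 2 (0.0504 each). Of 12 adipocyte genes 10 passed (11 when adjusted over the list alone), with a median ICC of 0.462 at percentile 99.97. Resistin Retn ran from 6.76 in RIIIS/J to 10.54 in BALB/cJ, leptin Lep was highest in KK/HlJ (5.52), and adiponectin Adipoq averaged 12.09. Lpl and Fabp4 did not pass. In contrast, 0 of 14 skeletal muscle genes passed (0 when adjusted over the list alone and 0 at an unadjusted p below 0.05; limma), with a median ICC of 0.0512 below all random lists. Skeletal muscle genes spread widely between arrays of a strain instead, with a within-strain SD of 2.94 for Acta1, 3.04 for Myh1 and 3.20 for Tnnc2. Of 9 cardiac muscle genes 7 passed (7 when adjusted over the list alone; median ICC 0.238, percentile 40.2). MA/MyJ was highest for all 9 and BXD42/TyJ lowest for 6, as for the atrial light chain Myl7 (12.40 against 6.92). Tnnt2 and Nppb did not pass. When the same arrays were omitted, 5 of the 7 lost their call: Mybpc3 (adjusted p = 0.199), Myl7 (0.380), Myl4 (0.313), Ryr2 (0.215) and Tnni3 (0.363). All 5 kept it with the thymocyte, squamous epithelium and skeletal muscle scores as covariates. Of 4 erythroid genes 3 passed (3 when adjusted over the list alone; median ICC 0.450, percentile 99.2), with Alas2 at 5.65 in BXD21/TyJ and 10.82 in AXB2/PgnJ. Of 5 Schwann cell genes S100b and Sox10 passed (5 when adjusted over the list alone; median ICC 0.183, percentile 24.3), and Sox10 lost its call under the same omission (adjusted p = 0.0999).

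**Figure D2:**
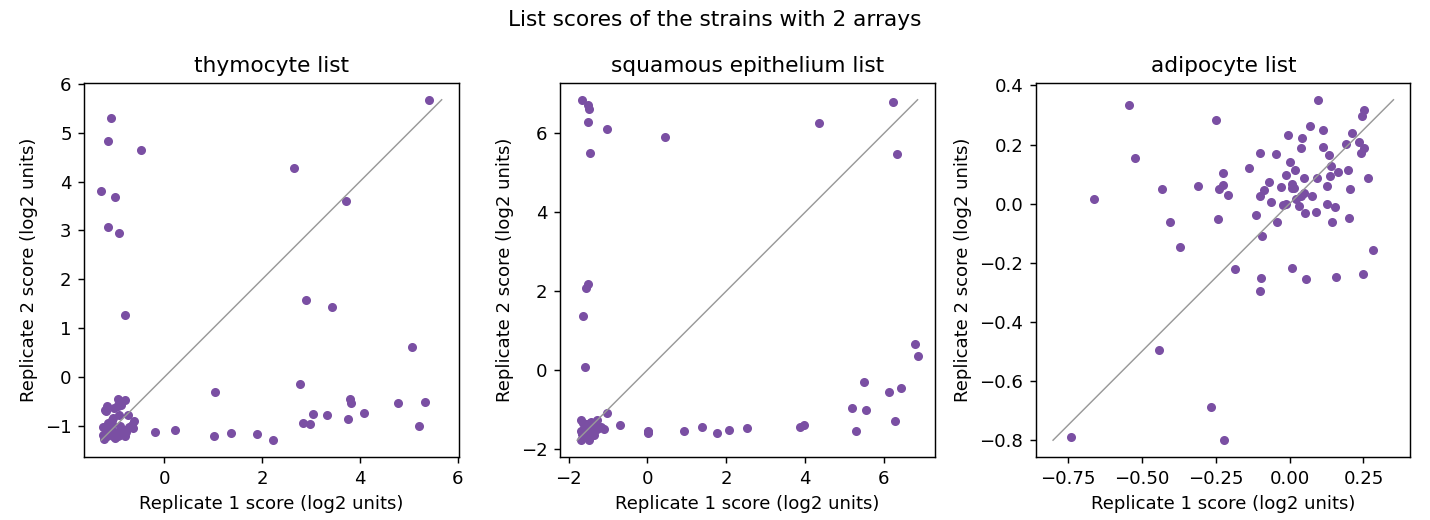
Score of replicate 1 against replicate 2 for the thymocyte, squamous epithelium and adipocyte lists in the 79 strains with 2 arrays (mean centred log2 value per array), with the line of equality. Many strains are high in 1 replicate only for the thymocyte list (up to 6.39 apart) and the squamous list (up to 8.50 apart), whereas the adipocyte score differs by at most 0.88.

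Clock genes differed between strains more than any of the random lists of their size: 11 of 13 passed (11 when adjusted over the list alone; median ICC 0.445). Per1 ran from 5.27 in RIIIS/J to 8.70 in C58/J, Npas2 from 3.49 in AXB10/PgnJ to 5.64 in BXD8/TyJ, and Dbp from 3.81 in MA/MyJ to 6.70 in BXD9/TyJ. Clock and Bhlhe41 did not pass. Of 13 xenobiotic and antioxidant genes 12 passed (12 when adjusted over the list alone; median ICC 0.320, percentile 87.4), with glutathione S-transferase Gstm1 at 7.46 in RIIIS/J and 10.86 in BTBR T<+> tf/J and haem oxygenase Hmox1 at 4.25 in CE/J and 8.48 in BXD8/TyJ. Aldh1a1 did not pass. Of 8 sterol synthesis genes 6 passed (6 when adjusted over the list alone; median ICC 0.370, percentile 99.01), with Sc5d from 4.83 in BXD2/TyJ to 8.19 in BXA14/PgnJ and Fdft1 from 8.74 in BXA11/PgnJ to 10.94 in BTBR T<+> tf/J. Srebf2 and Lss did not pass. Of 10 immediate early and heat shock genes, Nr4a1, Jun, Atf3, Fosb and Hspa1b passed (5 when adjusted over the list alone; median ICC 0.243, in the middle of the random lists). The genes Fos, Junb, Egr1, Dusp1 and Ier2 did not. Of 11 cell cycle genes 8 passed (9 when adjusted over the list alone; median ICC 0.200, percentile 85.5). RIIIS/J, whose thymocyte scores were 5.41 and 5.68, was highest for all 8, with Mki67 at 10.12 and Rrm2 at 9.08. With the arrays high in thymocyte or squamous genes left out, 6 of the 8 lost their call: Rrm2 (adjusted p = 0.157), Tpx2 (0.464), Top2a (0.0545), and Ccnb2 (-0.025), Aurka (-0.066) and Mki67 (-0.15), whose ICC turned negative. Mki67 also lost it in other settings, 15 in all. The adipocyte gene Car3 (0.0562), the xenobiotic gene Cyp1b1 (0.0553) and the Y-linked Uty (0.0602) lost their call under this omission as well.

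Some strain effect calls of list members depended on other settings as well. With only strains of consecutive numbers, besides Ucp1, Cox7a1 and Cox8b, these were the contractile genes Lmod1, Myh11, Mylk, Myocd and Tpm2, the matrix genes Bgn, Dcn, Emilin1, Mfap4 and Postn, and Dpt, Tie1, Ryr2, Tnni3, Ifi47 and Mx1. In the same setting they were Laptm5, Mrc1, Icam1, Ephx1, Nqo1, Txnrd1 and the cell cycle genes Aurka, Cdc20, Cdk1, Mki67 and Top2a (adjusted p = 0.0514 to 0.194 over all genes of this setting). With the array number block as a covariate, besides Ucp1, Irf7 and Ifit1, the calls of Mylk, Ryr2, Ifi47, Itgam, Laptm5, Mrc1, Icam1, Nqo1 and the same 5 cell cycle genes ended (0.0503 to 0.113, the highest for Icam1). With the BXD32/TyJ arrays those of Ifit1 (0.0558), Tie1, Dpt, Laptm5, Mrc1, Icam1 and Ephx1 ended (0.0565 to 0.0675). The omission of any of the 9 parental arrays ended the call of Mki67, and that of any A/J, C3H/HeJ or C57BL/6J array those of Laptm5 and Nqo1. Ephx1 and Ifit1 lost theirs without any A/J or C3H/HeJ array or C57BL/6J replicate 1 or 2. Mrc1 lost it without either C3H/HeJ array or C57BL/6J replicate 1 or 2, Tie1 without C57BL/6J replicate 1 or 2, and Top2a without C57BL/6J replicate 1 (0.0501 to 0.0760 for all these). A further quantile normalisation ended the calls of Ifit1 (0.0506), Itgam (0.0526) and Laptm5 (0.0533), trended and robust moderation those of Mki67 (0.0540) and Ephx1 (0.0532). The adipocyte, skeletal muscle and erythroid covariates ended that of Itgam (0.0608).

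The A/J parent of the AXB and BXA strains was compared with C57BL/6J to see which parental differences could segregate in that family. By the strongest probe set of each gene, A/J had more H2-D1 (10.14 ± 0.17, n = 2, against 3.97 ± 0.89, n = 3; log2 difference 6.17 ± 0.98 SE, adjusted p = 9.05e-06), Tmem87a (3.31 ± 0.41), the noncoding RNA Gas5 (3.10 ± 0.55), the guanylate-binding protein gene Gbp2b (3.03 ± 0.55) and Abhd1 (2.59 ± 0.45). Glo1, the methylglyoxal-detoxifying glyoxalase, was 2.32 ± 0.36 higher and the actin regulator Cap1 2.39 ± 0.35. Higher, too, were Olig1 by 2.32 ± 0.48, the nucleoside transporter Slc28a2 by 2.07 ± 0.44 and Wdfy1 by 2.21 ± 0.58. A/J had less Uqcr10 (4.59 ± 0.33 against 9.38 ± 0.34; -4.79 ± 0.52, adjusted p = 3.74e-11), Pttg1 (-4.29 ± 0.73), H2-Q10 (-3.91 ± 0.81), nicotinamide N-methyltransferase Nnmt (-3.55 ± 0.47) and Rpgrip1 (-3.39 ± 0.33, adjusted p = 7.42e-13). Peroxiredoxin Prdx2 was lower by -2.92 ± 0.37, Isoc2b by -2.65 ± 0.44, sclerostin Sost by -2.59 ± 0.64, resistin Retn by -2.38 ± 0.41 and Mul1 by -2.24 ± 0.42. For H2-D1, Tmem87a, Gbp2b, Abhd1, Olig1, Uqcr10, H2-Q10, Rpgrip1, Prdx2 and Mul1 the dimmer group's mean was no higher than Xist, a transcript of females, became in these males (4.63). The size of these differences is therefore uncertain. For H2-D1, Uqcr10, Prdx2 and Mul1 a brighter probe set was not called, so no bound on the gene's difference follows.

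Over all probe sets 144 differed between A/J and C57BL/6J, 60 higher and 84 lower in A/J (1991 at an unadjusted p below 0.05; limma), of which 123 changed more than 2-fold and 41 more than 4-fold. In 54 of the 144 the dimmer group lay no higher than Xist did. Of the list members only Retn was called. Adjusted over the list alone, 4 smooth muscle genes were lower in A/J (Lmod1, Kcnmb1, Myocd and Acta2, the last by -0.67 ± 0.25). So were Actc1 and Mybpc3 of the cardiac list, and Jchain was 3.06 ± 0.97 higher. The smooth muscle list as a whole was lower (camera, median -0.91, adjusted p = 3.04e-05 with the preset correlation). So was the cardiac list (median -1.35, adjusted p = 0.00729). Both had an adjusted p = 0.930 with an estimated correlation, which was 0.526 for the smooth muscle and 0.725 for the cardiac list. If these estimates hold, the p-values with the preset 0.01 are too small. The A/J arrays differed from each other in skeletal muscle score (-3.22 and 0.96), cardiac score (-0.25 and -1.79) and smooth muscle score (-1.53 and 0.36). The last difference, 1.89, was the largest of the 79 strains with 2 arrays. The count fell to 53 without A/J replicate 1 and to 95 without C57BL/6J replicate 1, and rose to 272 without C57BL/6J replicate 3. Without A/J replicate 1 the calls of Olig1 (adjusted p = 0.242), Wdfy1 (0.358), Slc28a2 (0.208), H2-Q10 (0.122) and Sost (0.930) ended. Wdfy1 also lost its call without A/J replicate 2 (0.356) and, with Sost, without C57BL/6J replicate 1 (0.262 and 0.181) or replicate 2 (0.315 and 0.0925), where Slc28a2 had 0.0752. The probe set with the highest mean of H2-D1 had the opposite sign (-0.30), and those of Uqcr10 (-0.02), Prdx2 (-0.14) and Mul1 (-0.43) were not called. The direction of H2-D1 is therefore uncertain, and so are the differences of the other 3 genes. In a fit of only the 9 parental arrays Wdfy1 (0.162), Slc28a2 (0.0988), Sost (0.507) and Mul1 (0.184) were not called.

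Between DBA/2J, parent of the BXD strains, and C57BL/6J, histocompatibility genes again differed. By its strongest probe set, H2-Ea was higher in DBA/2J (9.47 ± 0.07, n = 2, against 3.09 ± 0.13, n = 3; 6.38 ± 1.04, adjusted p = 1.68e-05). H2-D1 was also higher (6.34 ± 0.98). Cxcl14 was 28.4-fold higher (4.83 ± 0.80), followed by the scavenger receptor gene Stab2 (3.25 ± 0.68), the ribonuclease gene Rnase2a (3.16 ± 0.43), Sfi1 (3.06 ± 0.46), the mast cell protease gene Mcpt2 (2.87 ± 0.42), Cap1 (2.71 ± 0.47) and the interferon-inducible Ifi202b (2.68 ± 0.50). Lower in DBA/2J were Pttg1 (5.89 ± 0.54 against 11.50 ± 0.15; -5.61 ± 0.73, 49.0-fold, adjusted p = 2.90e-08), H2-Q10 (-4.16 ± 0.81), Tmem45b (-3.44 ± 0.47) and the amino acid transporter Slc7a8 (-3.25 ± 0.68). Lower, too, were the phosphatase inhibitor Ppp1r1a (-3.01 ± 0.44), Nnmt (-2.92 ± 0.47), Prdx2 (-2.87 ± 0.37), Rpgrip1 (-2.58 ± 0.33) and the stress gene Ddit4 (-2.13 ± 0.54, adjusted p = 0.0318). Pdxdc1 went both ways: the probe set with the highest ICC above was 4.01 ± 0.26 higher (adjusted p = 8.08e-24) and a second was -3.96 ± 0.42 lower (adjusted p = 1.18e-11) in DBA/2J. The direction of the gene is therefore uncertain. For both of these probe sets, H2-Ea, H2-D1, Stab2, Rnase2a, Mcpt2, Ifi202b, H2-Q10, Slc7a8, Prdx2 and Rpgrip1 the dimmer group lay no higher than Xist did. The size of these differences is uncertain too, and they set no bound on the gene's difference.

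In this contrast 117 probe sets were called, 64 higher and 53 lower in DBA/2J (1048 at an unadjusted p below 0.05; limma), with 99 over 2-fold and 43 over 4-fold. In 54 of the 117 the dimmer group lay no higher than Xist did. Of the list members, H2-Ea and P-selectin Selp (1.12 ± 0.29, adjusted p = 0.0375) rose. Adjusted over the list alone, Selp, Ccl7 (0.61 ± 0.18) and Ccl2 (0.77 ± 0.25) of the vascular inflammation list were higher and Nfkbia lower (-1.14 ± 0.35). Gbp2 was higher (1.30 ± 0.34), and Retn was lower (-1.49 ± 0.41). With the preset correlation camera called the macrophage list higher (median 0.69, adjusted p = 0.000142), the interferon list (0.26, 0.0461) and the vascular inflammation list (0.25, 0.0439) higher, and the smooth muscle list lower (-0.36, 0.0333), each with an adjusted p = 0.930 with an estimated correlation. The count fell to 72 without DBA/2J replicate 1 and to 54 without DBA/2J replicate 2. Of the 2 arrays, 1 DBA/2J array was lower in skeletal muscle genes than the other (-3.46 against -1.91). Ddit4 lost its call without each DBA/2J or C57BL/6J array in turn (adjusted p = 0.0538 to 0.640). Selp lost it without DBA/2J replicate 2 (0.999), C57BL/6J replicate 2 (0.151) or C57BL/6J replicate 3 (0.208). Stab2 (0.141) and Slc7a8 (0.154) lost it without DBA/2J replicate 1, and Ifi202b without DBA/2J replicate 2 (0.0556). With the array number block as a covariate, Ddit4 (0.0917) and Selp (0.0834) were not called, nor was Selp after a further quantile normalisation (0.114). In a fit of only the 9 parental arrays Ddit4 (0.0672), Selp (0.376) and Rpgrip1 (0.134) were not called. The probe sets with the highest mean of H2-D1 (0.03), Sfi1 (0.94) and Prdx2 (-0.05) were not called, nor was another of H2-Ea (1.06). The differences of these 4 genes are therefore uncertain.

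C3H/HeJ, parent of the BXH strains, differed from C57BL/6J in H2-D1 (by another probe set than above, 8.75 ± 0.13, n = 2, against 3.73 ± 0.35, n = 3; 5.02 ± 0.22, adjusted p = 9.10e-36). Also higher were Nme7, a nucleoside diphosphate kinase family gene (3.62 ± 0.31, 12.3-fold), Hba-a1 (3.49 ± 0.55), the B cell gene Ms4a1 (3.23 ± 0.86, adjusted p = 0.0312), the growth factor gene Hbegf (3.15 ± 0.39), Tmem87a (3.05 ± 0.41), Cap1 (3.01 ± 0.47), Ppp1r21 (2.81 ± 0.31) and Abhd1 (2.66 ± 0.45). Lower were Pttg1 (7.72 ± 0.19 against 11.50 ± 0.15; -3.79 ± 0.73, 13.8-fold), Slc7a8 (-3.34 ± 0.68), Prdx2 (-3.14 ± 0.37), Rpgrip1 (-3.02 ± 0.33) and Nnmt (-2.70 ± 0.47). Lower, too, were the cytochrome P450 genes Cyp2b10 (-2.66 ± 0.65, adjusted p = 0.0137) and Cyp2d22 (-2.62 ± 0.48), Fblim1 (-2.62 ± 0.57) and the urea cycle enzyme Asl (-2.52 ± 0.56, adjusted p = 0.00450). Pdxdc1 again split, with the first probe set 3.95 ± 0.26 higher and the second -3.76 ± 0.42 lower. A further H2-D1 probe set was lower (-1.48 ± 0.30, adjusted p = 0.00138). The direction of both genes is therefore uncertain. For H2-D1 and Pdxdc1 by their first probe sets, Ms4a1, Tmem87a, Abhd1, Slc7a8, Prdx2 and Rpgrip1 the dimmer group lay no higher than Xist did. This leaves the size of these differences uncertain, and they set no bound on the gene's difference.

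This contrast called 278 probe sets, 114 higher and 164 lower in C3H/HeJ (2906 at an unadjusted p below 0.05; limma), with 224 over 2-fold and 59 over 4-fold. In 89 of the 278 the dimmer group lay no higher than Xist did. Of the list members, Clec3b (1.50 ± 0.41, adjusted p = 0.0409) and Ms4a1 rose, as did the Y-linked Kdm5d (1.36 ± 0.28) and Uty (1.12 ± 0.25). Over all arrays the medians of Kdm5d and Uty were at most 4.54 and 4.14, below the highest Xist value of 4.63. The size of their differences is therefore uncertain. Retn (-1.68 ± 0.41, adjusted p = 0.0142) and Npas2 (-1.20 ± 0.28, adjusted p = 0.00909) fell. Adjusted over the list alone, 7 macrophage genes were higher, such as Ctss (2.10 ± 0.72) and Cd68 (1.51 ± 0.60). Higher, too, were 5 B cell genes of the lymphocyte list, such as Jchain (3.36 ± 0.97) and Cd79b (2.03 ± 0.83). The adventitial fibroblast and matrix gene Lum (2.18 ± 0.70), Ccl7 (0.57 ± 0.18), H2-Ea (2.82 ± 1.04) and Eif2s3y (2.28 ± 0.74) were also higher on the same count, and Nfkbia (-1.23 ± 0.35) and Gclm (-0.64 ± 0.21) lower. With the preset correlation camera called the macrophage (median 0.87, adjusted p = 5.07e-05), lymphocyte (1.68, 0.000174), interferon (0.55, 0.00401), skeletal muscle (3.14, 0.00729) and adventitial fibroblast (0.51, 0.0439) lists higher. The smooth muscle list was lower (-0.54, 0.0275), and each of these lists had an adjusted p = 0.930 with an estimated correlation. Median and test differed in sign for the adipocyte and circadian clock lists here, for the endothelial and sterol synthesis lists in A/J, and for the thoracic aortic disease, endothelial and Schwann cell lists in DBA/2J. Mean and test did so for the vascular inflammation and immediate early lists here, the cell cycle list in A/J and the xenobiotic list in DBA/2J. Camera called none of these lists in these contrasts. The skeletal muscle scores were 1.55 and 0.29 in C3H/HeJ against -3.02, -2.84 and 0.12 in C57BL/6J.

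The C3H/HeJ count ranged most with single arrays. It was 83 without C3H/HeJ replicate 1, 73 without replicate 2, 150 without C57BL/6J replicate 1, 108 without replicate 2 and 1123 without replicate 3. Clec3b lost its call without either C3H/HeJ array (adjusted p = 0.385 and 0.289) and without C57BL/6J replicate 1 (0.231) or 2 (0.0801). So did Ms4a1 (0.210, 0.455, 0.122 and 0.162) and Cyp2b10 (0.107, 0.340, 0.114 and 0.0514). Retn (0.121 and 0.337), Asl (0.105 and 0.120), Kdm5d (0.0568 and 0.0635) and Uty (0.153 and 0.0683) lost it without either C3H/HeJ array, and Retn also without C57BL/6J replicate 2 (0.142). Without C3H/HeJ replicate 1 the calls of Slc7a8 (0.0603), Fblim1 (0.349) and the further H2-D1 probe set (0.150) ended, and without replicate 2 those of Nnmt (0.0693) and Npas2 (0.425). The probe sets with the highest mean of Hba-a1 (0.50), Prdx2 (-0.20) and Fblim1 (-1.05) were not called, which leaves these differences uncertain, and that of H2-D1 is the one that was lower. In a fit of only the 9 parental arrays Fblim1 (0.366), Npas2 (0.0544), Kdm5d (0.117) and Uty (0.0966) were not called. Clec3b was not called with the array number block as a covariate (0.0711) or after a further quantile normalisation (0.0759).

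Some differences from C57BL/6J were shared by the other parents. Called in all 3 contrasts were 25 probe sets, all with the same sign. Among them were Pttg1, Rpgrip1, Prdx2, Nnmt and alcohol dehydrogenase Adh1 (-1.81, -1.25 and -1.64 in A/J, DBA/2J and C3H/HeJ) on the low side and Cap1, Tmem87a and Glo1 (2.21, 1.15 and 1.42) on the high side. Adh1 was chosen after its values were seen. The pairs of contrasts shared 34 (A/J and DBA/2J), 69 (A/J and C3H/HeJ) and 53 (DBA/2J and C3H/HeJ) calls of the same sign and 0 of opposite sign (limma). Independent lists would share 0.371, 0.923 and 0.716. Simulated unchanged groups against the same controls shared 0. With no true differences hardly any calls could arise there, so this 0 does not bear on how shared controls affect real calls. Fold changes correlated across probe sets at 0.514, 0.699 and 0.581 against 0.399, 0.400 and 0.400 in the simulation. Covariances were 0.0857, 0.168 and 0.109 against 0.0595, 0.0598 and 0.0597. The 3 control arrays were too few to be split, so part of the excess may come from the shared controls.

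Parental differences were next followed into the recombinant inbred strains, in which each locus is fixed for the allele of either parent. H2-D1 lay nearer the A/J mean in 13 of 28 AXB and BXA strains and nearer the C57BL/6J mean in the others, with strain means from 3.20 to 10.83 (within-family adjusted p = 2.66e-09, limma). In the same family Uqcr10 and Pttg1 each lay nearer A/J in 17 of 28 strains and H2-Q10 in 13 of 28. In 27 BXD strains H2-Ea lay nearer DBA/2J in 18, with strain means from 2.82 to 10.62, H2-D1 in 17, Pttg1 in 16 and Cxcl14 in 14. In the 10 BXH strains H2-D1, by the probe set called in C3H/HeJ, lay nearer C3H/HeJ in 3, with strain means from 3.42 to 9.14, and Pttg1 and both probe sets of Pdxdc1 in 5. None of these 12 splits differed from equal shares (exact binomial test, two-sided, p = 0.122 to 1, adjusted p = 0.828 to 1). AXB19/PgnJ, AXB19a/PgnJ and AXB19b/PgnJ counted as separate strains, though their names point to a common line. Their H2-D1 means were 3.51, 3.66 and 3.50. If they are related, the family holds fewer independent strains than 28.

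**Figure D3:**
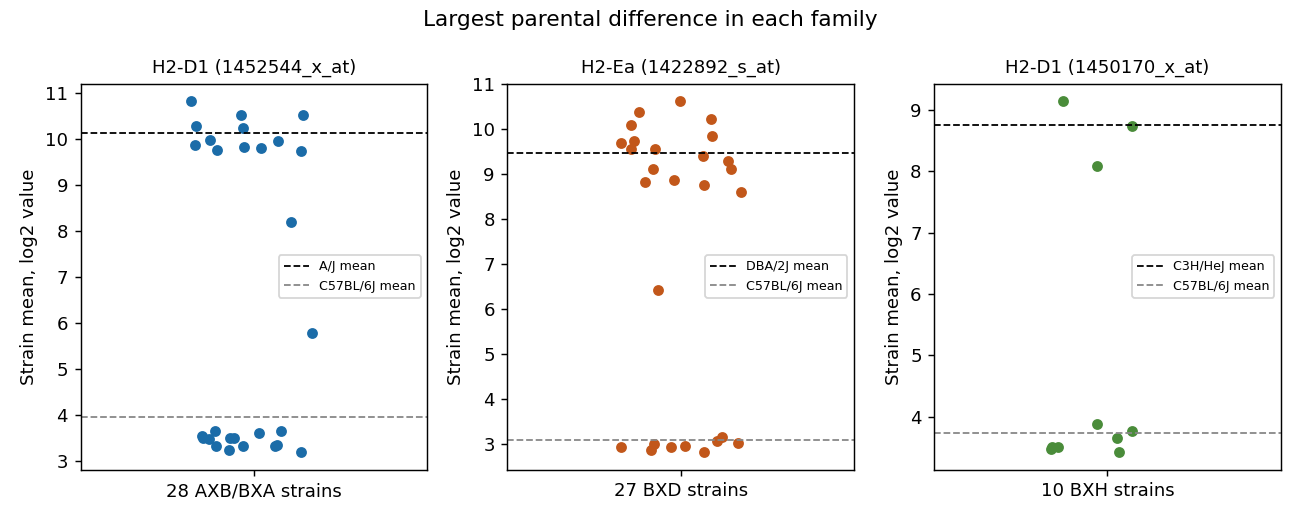
Strain means (log2) of H2-D1 in 28 AXB and BXA strains, H2-Ea in 27 BXD strains and H2-D1 by a second probe set in 10 BXH strains, spread sideways for display. The black dashed line is the mean of A/J, DBA/2J or C3H/HeJ and the grey dashed line that of C57BL/6J; most strain means lie near a parent, while BXA2/PgnJ (5.78), BXA16/PgnJ (8.20) and BXD19/TyJ (6.43) lie between.

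Of the 144 probe sets called between A/J and C57BL/6J, 102 (70.8%, 95% interval 62.7 to 78.1) differed between the AXB and BXA strains, against 3.38% of the other probe sets. The shares were 112 of 117 (95.7%, 90.3 to 98.6) against 14.6% in the BXD strains and 92 of 278 (33.1%, 27.6 to 39.0) against 0.857% in the BXH strains, of which only 9 strains could be tested. Probe sets above the median level gave 68.7%, 95.9% and 32.2% in AXB/BXA, BXD and BXH, against 5.34%, 29.7% and 1.40%. With 1 probe set per gene the shares were 63.2%, 95.9% and 23.8%, against 3.65%, 17.1% and 0.847%. With the BXD32/TyJ arrays the BXD share was 93.8% against 6.85%. The spread for the parental contrasts came from all strains, so probe sets with little spread could pass both tests more easily. Differences followed the family that has the parent. The 110 probe sets called for A/J but not DBA/2J varied more in AXB and BXA than in BXD strains (median log2 variance ratio 0.68). The 83 called for DBA/2J but not A/J varied less (-1.98), a difference of 2.66 (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give). Calls in C3H/HeJ were not considered in this choice. Without the arrays high in thymocyte or squamous genes the shares were 21.4% of 280 in AXB/BXA, 73.9% of 188 in BXD and 9.21% of 630 in BXH, against 0.943%, 4.71% and 0.253% of the other probe sets. Those segregating numbered 60, 139 and 58, so in BXD the number rose while the share fell. No parental array was omitted, so the larger numbers called between the parents came from the spread in the fit. With the thymocyte, squamous epithelium and skeletal muscle scores as covariates the shares were 66.8% of 232, 90.3% of 155 and 19.3% of 508. Of the other probe sets 6.74%, 14.8% and 1.16% segregated. With the adipocyte, skeletal muscle and erythroid scores as covariates the shares were 44.5% of 1667, 84.8% of 230 and 3.76% of 4388, against 10.9%, 12.9% and 1.39%. The probe sets segregating numbered 741, 195 and 165, more than the 102, 112 and 92 above. The BXH share thus depends much on this choice, through the number called between the parents.

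The families were compared with each other to ask whether their mean levels differ as their parents do. AXB and BXA strains had less H2-Ea than BXD strains (3.89 ± 1.17, n = 28, against 7.21 ± 3.15, n = 27; -3.32 ± 0.58, adjusted p = 0.000182), less Uqcr10 (-2.90 ± 0.42, adjusted p = 5.65e-06), less Cxcl14 (-2.12 ± 0.40) and less Serpina1b (-1.83 ± 0.45). They had more Fbp1 (1.86 ± 0.33), Tmem45b (1.45 ± 0.31), Erdr1 (1.66 ± 0.44) and the actin-bundling gene Baiap2l1 (1.50 ± 0.30). Pdxdc1 was 2.12 ± 0.42 higher by the second probe set and -2.34 ± 0.42 lower by the first. The dimmer family's mean was no higher than Xist for H2-Ea, Serpina1b, Fbp1, Baiap2l1 and the first Pdxdc1 probe set. The size of these differences is therefore uncertain. Of the list members the endothelial genes Emcn and Egfl7, Car3, Gbp2, H2-Ea, Selp and the clock gene Per3 were lower and Fdps and Hspa1b higher. Adjusted over the list alone there were 5 sterol synthesis, 4 endothelial and 3 circadian clock calls and 2 each of the adipocyte and MHC lists. There was 1 each of the interferon, vascular inflammation, xenobiotic and antioxidant, and immediate early and heat shock lists. Without the arrays high in thymocyte or squamous genes Cxcl14 (adjusted p = 0.236), Serpina1b (0.362), Baiap2l1 (0.0694) and Erdr1 (0.0802) were not called. In this contrast 495 probe sets were called (203 higher, 292 lower; 3017 at an unadjusted p below 0.05; limma). Of these, 399 (80.6%, 76.8 to 84.0) had the sign of A/J minus DBA/2J, against 49.1% of all probe sets. Erdr1 did not, with -0.33 between the parents. Erdr1 was not called with the adipocyte, skeletal muscle and erythroid scores as covariates (0.0702). Another probe set of Uqcr10 had the opposite sign (0.055). Without AXB19a/PgnJ and AXB19b/PgnJ the count was 414 in this contrast, 69 for AXB/BXA minus BXH and 38 for BXD minus BXH.

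BXH strains stood apart from the AXB and BXA strains by more Uqcr10 (AXB/BXA minus BXH -2.85 ± 0.57, adjusted p = 0.00605), Hba-a1 (-1.55 ± 0.34) and H2-D1 (-1.53 ± 0.34, by the probe set called in C3H/HeJ). They had less follistatin Fst (1.26 ± 0.29), Fblim1 (0.97 ± 0.22) and the glycosyltransferase gene Galnt2 (0.75 ± 0.14). They stood apart from BXD strains by less H2-Ea (BXD minus BXH 3.45 ± 0.80, adjusted p = 0.0362), Fblim1 (0.97 ± 0.22) and Jade1 (0.91 ± 0.20). They had more H2-Q10 (-3.00 ± 0.67), Tmem45b (-2.30 ± 0.43) and Abhd1 (-1.98 ± 0.41). The differences of H2-D1, H2-Ea and Abhd1 have a dimmer mean no higher than Xist and are of uncertain size. Against AXB/BXA, 72 probe sets were called (17 higher, 55 lower; 1625 unadjusted) and 68 of them (94.4%, 86.4 to 98.5) had the sign of A/J minus C3H/HeJ. Against BXD, 41 were called (12 higher, 29 lower; 1163 unadjusted) and 40 (97.6%, 87.1 to 99.9) had the sign of DBA/2J minus C3H/HeJ. No list member was called between AXB/BXA and BXH (limma; adjusted over the list alone, 1 each of the adipocyte, circadian clock and sex chromosome lists). Only H2-Ea was called between BXD and BXH (adjusted over the list alone, 2 MHC, 2 vascular inflammation, 1 endothelial and 1 interferon). The call of H2-Ea between BXD and BXH ended with the BXD32/TyJ arrays (adjusted p = 0.0570) and with only strains of 2 or more arrays (0.0863). With the latter ended those of H2-Q10 (0.0658), Jade1 (0.0863) and Fblim1 (0.0658, and 0.0558 against AXB/BXA). With the adipocyte, skeletal muscle and erythroid scores as covariates H2-Ea (0.0656), Jade1 (0.0661), H2-Q10 (0.0694), Fst (0.101) and, against AXB/BXA, Uqcr10 (0.0540) were not called. Without the arrays high in thymocyte or squamous genes, Fst (0.149), Fblim1 (0.247 and 0.220), Hba-a1 (0.0844), H2-D1 (0.0857) and Jade1 (0.118) were not called. Other probe sets of Fblim1 (0.20 and 0.14), Galnt2 (0.05), Hba-a1 (-0.10) and Jade1 (0.05) were not called either. Those of Uqcr10 (0.069) and H2-D1 (0.43) in AXB/BXA minus BXH had the opposite sign.

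The alleles written in strain names were looked up directly. Tlr4, the endotoxin receptor, was 3.51 ± 0.03 and 3.63 ± 0.03 by its 2 probe sets in BXD29-Tlr4<lps-2J>/J (n = 2). This was below all 26 other BXD strains (4.04 ± 0.22 and 4.88 ± 0.32). Cep290 was 3.03 ± 0.23 in BXD24/TyJ-Cep290<rd16>/J (n = 2) against 3.10 ± 0.12 in the others. The Cep290 values are no higher than Xist in these males, so they say nothing on that allele. The first Tlr4 probe set was as dim in all BXD strains. By the second, the means of the other BXD strains were 4.48 to 5.76. In the check of sex chromosome genes, 3 of 4 differed between strains (3 when adjusted over the list alone). Xist was at most 4.63 in all arrays and the Y-linked Eif2s3y had a median of 7.18, with 16 arrays below 5. Across the 93 strain means, the smooth muscle score fell with the lymphocyte score (r = -0.271, permutation p = 0.00826, adjusted p = 0.0743; rho = -0.200, p = 0.0549). This did not pass over the 9 correlations computed. The r was -0.347 without the 2 most extreme strains and -0.308 and -0.204 within the blocks of array numbers. It was unrelated to the adipocyte (r = 0.00131, rho = -0.102) and skeletal muscle scores (r = 0.100, rho = 0.134; permutation p = 0.990 and 0.338).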

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

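Chosen only after the result was seen were the test on the held-out squamous list, the test on the share of probe sets lower in the other parent, the gene lists for thymus, squamous epithelium and skin, and the array correlations. Single arrays stood apart from the others of their strain in 5 of 83 tests, where chance picks out about 1 in 20. The tests covered 24 list scores in each of the 3 strains with 4 arrays and named genes over the 10 BXH strain means. AXB19b/PgnJ replicate 3 had a sterol synthesis score of -0.15 (others 0.22 to 0.26). AXB19b/PgnJ replicate 4 had a thymocyte score of 3.99 (others -1.03 to -0.84). BXD19/TyJ replicate 2 had an adventitial fibroblast score of -0.17 (others 0.43 to 0.53) and an immediate early and heat shock score of -0.14 (others -0.46 to -0.42). BXD19/TyJ replicate 1 had an interferon response score of 1.58 (others -0.28 to 0.01). Of the 2 BXD32/TyJ arrays, which were left out of the main fits, replicate 2 had a squamous epithelium score of 5.92, with 18 other arrays higher and all arrays between -1.78 and 6.85.

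Thymocyte genes were high in some arrays and low in the other array of the same strain: in 30 of 79 strains with 2 arrays the thymocyte scores differed by more than 1, up to 6.39 in BXA7/PgnJ, and in RIIIS/J replicate 2 the genes Satb1, Dntt, Cd8a and Rag1 reached 12.15, 11.16, 10.85 and 10.70 against medians of 5.94, 3.20, 4.28 and 2.98 over all arrays, with no gene shared with another list and only Satb1 of the 8 most abundant having a median above that of all values, 4.72. The tables argue against a difference between strains as the whole cause, since the ICC of the score was 0.156 with an upper 95% bound of 0.348. RNA from thymus, which lies near the aortic arch, is a candidate source: a list of 7 thymus genes that had not been looked at before, among them Ccl25 and Myb, followed the score with r = 0.975 (0.966 to 0.981; rho = 0.690; permutation p = 1e-05 for each, the smallest possible, adjusted p = 1e-05 over 6 relations; 0.973 without the 2 most extreme arrays, 0.979 and 0.970 within the blocks of array numbers), as did the cell cycle score (r = 0.934, rho = 0.675, the same p; 0.937, 0.931 and 0.948), although Foxn1 reached only 4.05 and Aire 7.28. Thymocytes that had entered the aorta from the blood remain open and untested, as does a strain difference in part of the signal, for example in RIIIS/J, where both arrays were high (5.41 and 5.68).

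Genes of keratinised squamous epithelium were likewise high in single arrays: the score differed by more than 1 in 31 of 79 strains, up to 8.50 in BXA26/PgnJ, and in BXD36/TyJ replicate 1 the genes Krt4, Lor, Krt13 and Sprr3 reached 12.80, 12.22, 12.17 and 11.73 against medians of 3.21, 3.40, 3.09 and 3.50, with no gene shared with another list and none of the 8 most abundant having a median above 4.72. The tables argue against a strain difference as the whole cause (ICC 0.124, upper bound 0.318) and against skin, whose keratins Krt1, Krt10 and Krt2 stayed at or below 5.57, 6.03 and 3.92, though Krt15 reached 9.17, and whose score rose by 0.0655 per unit (0.0587 to 0.0723). The oesophagus, which runs beside the thoracic aorta, is a candidate source: a held-out list, of which Krt5, Krt14, Trp63 and Calml3 had been looked at earlier, followed the score with r = 0.924 (0.900 to 0.943; rho = 0.618; permutation p = 1e-05 for each, the smallest possible, adjusted p = 1e-05 over 6 relations; 0.919 without the 2 most extreme arrays, 0.932 and 0.915 within the blocks), and its 5 genes that had not been looked at before did so (Tgm3, Serpinb5 and Sfn reached 8.98, 8.49 and 7.20, but Krt6a and Krt6b only 4.24 and 4.88) with r = 0.940 (rho = 0.588, the same p; 0.936, 0.946 and 0.936). The score also went with the skeletal muscle score (r = 0.435, rho = 0.350, the same p; 0.418, 0.438 and 0.438), and Krt4, Krt13, Krtdap and Rptn were among the 86 probe sets that differed between false pairs of neighbouring arrays. Apart from skin, which squamous organ it was, and whether handling on a day set its amount, were not tested and stay open.

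Probe sets of the same gene often gave different parental differences: over 143 pairs of a called probe set and another bright probe set, the other's log2 difference was a median 0.475 of the called one's (0.307 to 0.614), with 65 ratios above 0.5, 53 below 0.25 and 25 of opposite sign, and 21 of the others were called themselves, 3 of them the opposite way. A single transcript level shared by all probe sets of a gene and probe-specific signal cannot be told apart, because the interval spans the value of 0.5 set in advance. Probes designed on the C57BL/6J sequence could lose signal at variants of the other strain: 301 of 539 calls over the 3 contrasts (55.8%, 51.5 to 60.1, with probe sets called more than once taken as independent; 58.3% in A/J, 45.3% in DBA/2J and 59.0% in C3H/HeJ) were lower in the other parent, or 225 of 408 distinct probe sets (55.1%, 50.2 to 60.04), which neither reaches the 60% written for this cause nor excludes it. Probe sequences and strain variants were not used here, and differences in transcript ends, related gene copies and true expression differences all stay open. Segregation does not separate them, since a variant under a probe is inherited like a change in expression.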

How the results depend on the processing

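The omission of arrays high in thymocyte or squamous genes, the thymocyte, squamous epithelium and skeletal muscle covariates, and the fit without C57L/J replicate 1 were tests chosen after the data had been seen. The other alternatives were planned. Of the values recomputed for single genes, 3428 of 3594 for the strain effect, 1112 of 1190 for the parents and 208 of 239 for the families kept their direction and their side of the threshold, 159, 74 and 27 lost their call and 7, 4 and 4 reversed. An ICC has no direction: the 7 strain effect values are ICCs that turned negative. Their calls ended too, but they are not among the 159. A gene counts once per setting here, and many settings leave out only 1 array. The omission of arrays high in thymocyte or squamous genes held 54 of the calls so counted as lost, the most of any setting, besides the 7 negative ICCs. With the adipocyte, skeletal muscle and erythroid covariates, the number of members passing the strain effect stayed the same within 1.5 times in 22 of 23 lists. Leaving out single parental arrays gave ranges of 53 to 272 for A/J, 54 to 130 for DBA/2J and 73 to 1123 for C3H/HeJ. The strain effect ranged from 9948 to 10957 and was 11328 without C57L/J replicate 1. A strain with 1 remaining array was assumed to vary like the others. No paired analysis was possible because the labels give no replicate numbers that pair arrays across strains. With 1 probe set per gene, counts were lower because fewer probe sets were tested: 5759 for the strain effect, 76, 49 and 151 for A/J, DBA/2J and C3H/HeJ, and 242, 24 and 20 for AXB/BXA minus BXD, AXB/BXA minus BXH and BXD minus BXH, with 23.8% segregating in BXH and 100% of signs matching in AXB/BXA minus BXH. There, because another probe set stands for the gene, signs reversed for H2-D1 in A/J (-0.30), C3H/HeJ (-1.48) and AXB/BXA minus BXH (0.43), Pdxdc1 in DBA/2J (-3.96), C3H/HeJ (-3.76) and AXB/BXA minus BXD (2.12), and Uqcr10 in AXB/BXA minus BXD (0.055) and AXB/BXA minus BXH (0.069). With the adipocyte, skeletal muscle and erythroid scores as covariates the parental counts were 1667, 230 and 4388, 44.5%, 84.8% and 3.76% segregated in AXB/BXA, BXD and BXH (10.9%, 12.9% and 1.39% of the other probe sets), and 82.2% of list members passed the strain effect, 4 skeletal muscle genes among them. The cause was not tested. With thymocyte, squamous epithelium and skeletal muscle covariates the strain effect had 10653 calls, DBA/2J 155 and the families 460, 92 and 47, all within 1.5 times. A/J had 232 and C3H/HeJ 508. The shares segregating were 66.8%, 90.3% and 19.3% in AXB/BXA, BXD and BXH (6.74%, 14.8% and 1.16% of the other probe sets). In this setting 8 calls of single genes ended. The cause of the moves in A/J, C3H/HeJ and BXH was not tested. Of all arrays, BXD32/TyJ included, 73 lay above 1 on either score and 115 did not. Without the 73 the calls were 6865 for the strain effect, 280, 188 and 630 for the parents, and 160, 22 and 19 for the families. The shares segregating were 21.4%, 73.9% and 9.21% (0.943%, 4.71% and 0.253% of the other probe sets). The ICC turned negative, and the call ended, for Ccnb2 (-0.025), Aurka (-0.066), Mki67 (-0.15), Acta2 (-0.033), Lmod1 (-0.011), Myh11 (-0.11) and Mylk (-0.038). No parental array was among the 73: the highest thymocyte score was -0.595 (C3H/HeJ replicate 2) and the highest squamous score -0.935 (C57BL/6J replicate 3). The parental log2 differences were therefore unchanged, and the higher parental counts came from the spread estimated on the remaining arrays. For the other counts fewer arrays and strains enter, and beyond that the cause was not tested. An adjusted p threshold of 0.01 gave 6471 for the strain effect, strains with consecutive array numbers 6852, and random pairs 0 (635 at an unadjusted p below 0.05; limma) where false neighbouring pairs gave 86. Only the 9 parental arrays gave 78, 65 and 152, and only strains with 2 or more arrays gave 19 for BXD minus BXH, both with fewer arrays in the fit. With an estimated correlation camera called 0 lists (2 at an unadjusted p below 0.05). For the lists called with the preset 0.01 the estimates were 0.153 (vascular inflammation) to 0.870 (skeletal muscle). If these estimates hold, the p-values with the preset correlation are too small. The correlation of smooth muscle and skeletal muscle scores went from 0.10 to -0.00875 with the first principal component as the score, and the cause of that move was not tested. Dim probe sets limit what can be seen: 2566 calls fell below the median level and 7809 above it.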

Other observations

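Strain accounted for only part of the main axes of variation, with ICCs of 0.198, 0.259, 0.0483, 0.330 and 0.383 for the first 5 principal components. The first principal component held 26.7% of the variance and went with the array median (|r| = 0.614), the second held 15.0% and went with the thymocyte score (|r| = 0.926), and the third held 9.43% and went with the squamous epithelium (|r| = 0.901) and skeletal muscle (|r| = 0.668) scores; these are descriptions over arrays and not tests. The skeletal muscle score itself differed by more than 1 between the arrays of 57 of 79 strains, by up to 7.96 in BXD42/TyJ, and had an ICC of 0.0297. By comparison the smooth muscle score differed by more than 1 in 13 strains, by at most 1.89 (A/J), the macrophage score in 4 and the adipocyte score in 0, by at most 0.88 (BXH9/TyJ). The 3'-to-5' difference of Gapdh, a sign of RNA quality, lay between 0.000494 and 1.41 (median 0.233) and that of Actb between 0.91 and 2.73 (median 1.57). The BXD32/TyJ arrays, which were left out of the main fits, had macrophage scores of 0.34 and -0.05, within the range of all arrays (-1.17 to 1.50). In a limma fit with strain, in which only the 5 strains with arrays in both number blocks inform the block, 0 probe sets were called for it, with 813 at an unadjusted p below 0.05.

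The condition that both number blocks hold the clock relation was chosen after its values were seen; the other tests here were written down before. Genes called between parents may be inherited as local blocks: turned to the parental direction, called genes within 50 genes of each other correlated across recombinant inbred strains with a mean r of 0.508 (70 pairs), against 0.047 for 24871 pairs on different chromosomes, a difference of 0.461 where permuted gene positions gave -0.0747 to 0.0772 (permutation p = 0.0001, the smallest possible). Genotypes were not used, so this does not locate any block.

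Clock genes may differ between strains because tissue was taken at different circadian phases. Across strain means the average of Arntl and Npas2 ran against that of Dbp, Per3, Tef and Nr1d2 with r = -0.523 (-0.656 to -0.357; rho = -0.364; permutation p = 1e-05, the smallest possible, and 0.00026; -0.485 without the 2 most extreme strains). The pooled value reached the -0.5 set in advance, but r was -0.126 in the first number block and -0.754 in the second (44 strains each), so phase and an inherited difference cannot be told apart; no time of collection was used here.

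Random regroupings were used to ask whether chance could give as many calls. Of 100 regroupings, the real one included, 1 reached the 10375 calls of the strain effect (highest other 48), 1 the 495 of AXB/BXA minus BXD (highest other 18) and 1 the 41 of BXD minus BXH (highest other 12), so chance can be excluded for these at the level of 0.05. These regroupings ignore the array numbers, which arrays of a strain mostly share as neighbours: false pairs of neighbouring arrays gave 86 calls, above the 48, against 4121 for true strains on 122 of the same arrays. For AXB/BXA minus BXH 4 of 100 reached 72 calls and the highest other had 4749. This is under the level of 0.05 too, but a regrouping with so many calls points to a structure of the samples, which was not examined and stays open.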
